A study of Mus musculus with 12 samples.

How the data were processed

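Gene counts of 12 libraries of mouse splenic CD11c+ cells were analysed, 3 for each combination of genotype (WT, or KO after the label) and treatment (untreated, or attenuated Salmonella typhimurium). Per the labels' protocols, spleen cells were depleted of CD90.2, CD45R and CD49b positive cells with biotinylated antibodies and anti-biotin microbeads, and CD11c positive cells were then selected. Treated cells received bacteria at a multiplicity of infection of 10 for 30 min and were kept for 3 h after washing. Total RNA was reverse transcribed with random hexamers and sequenced as paired reads on an Illumina NovaSeq, per the labels' protocols. Raw counts per gene were deposited, after base calling with CASAVA 1.8 and alignment with HISAT2 (version not given) to mm10, per the submitters' processing notes. The counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited count table held 54532 genes, of which 203 shared a symbol with another gene, and the 12 columns were used as separate libraries. Coordinates are those of the deposited table (mm10).

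The test, the samples, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups, which left 14293. Libraries were scaled by TMM factors, and a quasi-likelihood model with robust estimation was fitted to all 12 libraries with a term per group. The contrasts were the response to bacteria in WT and in KO, the genotype difference untreated and treated, and the interaction, which is the KO response minus the WT response. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and 0.05 was the threshold. Standard errors (SE) of log2 fold changes were taken as the absolute fold change over the square root of F. Levels are CPM, counts scaled to a common library size with the TMM factors, given as mean ± SD of 3 libraries. Where a group held 0 counts of a gene, a lower bound of the fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with a 95% counting interval was given in place of a fitted fold.

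Lists of genes, 36 in number with 914 symbols, were written from general knowledge. Of the symbols, 900 were found and 848 were tested. They covered cytokines, chemokines, type I interferon response, NF-kB, Toll-like receptors, inflammasome, maturation, MHC class I and II, autophagy, lysosome, endolysosomal channels, nucleosides, phagocytes, immediate early genes, ER stress, glycolysis, oxidative phosphorylation, mitochondrial genes, ribosomal proteins, cholesterol synthesis, LXR and lipids, cell cycle, p53 targets, sex-linked genes and 11 cell types. Each was tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with a correlation estimated from the data, with adjustment over the 36 lists of a contrast. Members past the threshold were counted after adjustment over all genes and over the list alone.

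The difference in size of the response was the median over genes of KO minus WT response in log2 CPM (prior count 2). It was taken over genes whose mean response reached 1 log2 and passed the threshold, and tested by an exact permutation of genotype within treatment over 400 arrangements. That permutation is exact only if the genotypes do not differ within a treatment. Genes within 20 Mb of Slc29a3, and in windows of 5 Mb and 1 Mb, were compared with all tested genes by Fisher's exact test.

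Named genes followed a rule: a fixed set (Slc29a3, Mcoln1, Tfeb, Tfe3, Slc15a4, Tnf, Il6, Il1b, Il12b, Ifnb1, Cxcl10, Map1lc3b, Sqstm1, Tlr4 and Myd88), the 8 genes with the largest change in each direction without overlap between groups and with at least 5 CPM, and up to 4 members per list. The text prints a part of these, mostly genes whose call held under every alternative. Genes of the interaction with the block within genotype, and neighbours of Slc29a3 within 1 Mb, were outside the rule and were chosen after the result was seen.

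Libraries carry numbers 1 to 3 in each group, and the labels do not say what a number marks. Deviations from group means of libraries with the same genotype and number correlated with r from 0.226 to 0.53 in all 6 pairs across treatment, so the numbers were taken to pair them, a pairing that comes from the data and not from the labels. The fit with this block is given beside calls of printed genes and of lists that it changed, and beside the counts of genes.

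Alternatives were DESeq2 size factors, upper-quartile factors, library totals alone, the DESeq2 1.42.0 Wald test, limma-voom, other filters, protein-coding genes, only the groups compared, a fold threshold, replicate blocks, a sex term, fry for lists, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

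Tested genes held at least 99.87% of the counts of each library. Simulated counts used the library sizes of the data and gene means averaged over all libraries, with 66 or 67 genes changed at each fold. So few changes make the adjustment stricter than where many genes change, so the shares recovered can understate those in the data. The fit recovered 4.5%, 41.8% and 71.2% of genes changed 1.5-fold, 2-fold and 4-fold in the WT response (13997 genes). In the KO response (14026 genes) it recovered 9%, 38.8% and 78.8%. It recovered 7.5%, 34.3% and 75.8% in the untreated genotype comparison (14031 genes), 9%, 41.8% and 84.8% in the treated one (14005 genes), and 0%, 19.4% and 56.1% in the interaction (14010 genes), where 7 of 57 calls were false.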

Results

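RNA was sequenced from dendritic cells (DCs), the antigen-presenting cells that start T cell responses, isolated from mouse spleen. The labels describe the preparation as a mixture of conventional type 1 DCs (cDC1, which carry CD8) and conventional type 2 DCs (cDC2, which carry SIRPα). Cells came from wild-type (WT) C57BL6 mice or from mice lacking Slc29a3, the gene of ENT3, a nucleoside transporter of lysosomes. Libraries of the second kind are called KO here, after their labels. Cells were left untreated or were given an attenuated strain of Salmonella typhimurium at a multiplicity of infection of 10 for 30 min, washed, and kept for a further 3 h. The 4 groups held 3 libraries each, numbered 1 to 3. The labels do not state that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical between numbers 2 and 3. In every group number 1 had Y-linked counts and at most 1 count of Xist, unlike numbers 2 and 3. The total of gene counts per library ran from 16432936 to 18107470 in untreated WT, 15693172 to 24074596 in treated WT, 15814761 to 18561946 in untreated KO and 15946516 to 19087007 in treated KO libraries. The series title places SLC29A3 in antibacterial signalling from the phagosome and in autophagy through TRPML1, the lysosomal cation channel encoded by Mcoln1.

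The largest differences between libraries followed genotype and treatment. The first principal component held 39.4% of the variance and parted WT libraries (scores from -61.9 to -44.3) from KO libraries (26.2 to 67.0). The second held 28.0% and parted untreated from treated libraries. Along the first component the KO libraries numbered 1 (32.4 untreated, 26.2 treated) lay nearer to WT than the other KO libraries did (58.7 to 67.0).

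**Figure D1:**
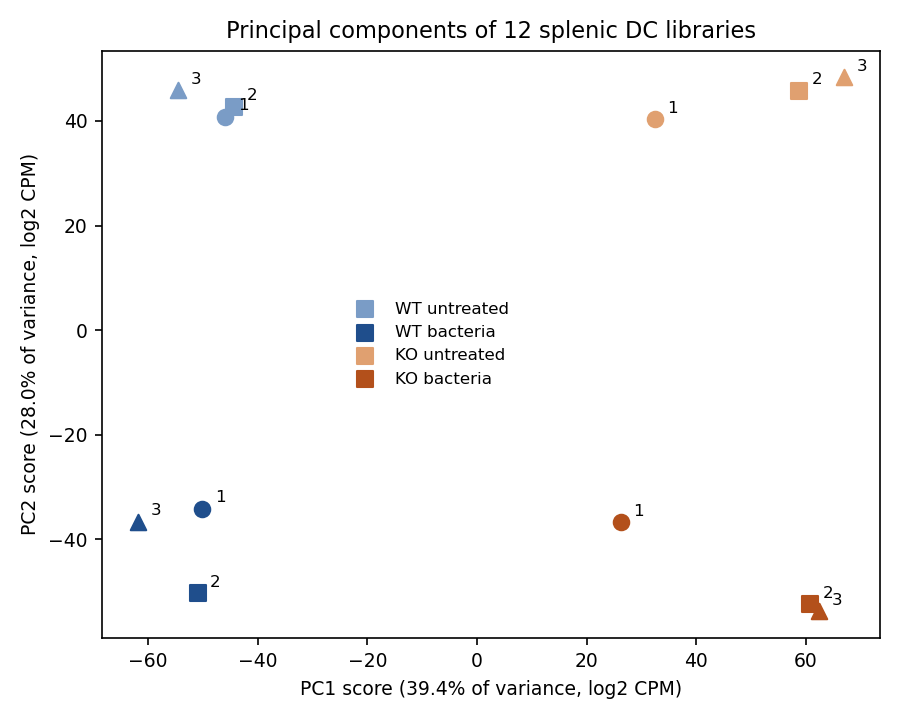
Scores of the 12 libraries on the first and second principal components of log2 CPM (normalised counts scaled to a common library size), with colour for genotype and treatment and shape for the replicate number. WT and KO libraries separate along the horizontal axis (39.4% of variance) and untreated and treated libraries along the vertical axis (28.0%).

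Slc29a3 itself (ENSMUSG00000020100, mm10 chromosome 10, 60712072 to 60752794, minus strand) was counted in all 12 libraries. Its normalised level in untreated cells was 110.2, 99.2 and 103.9 CPM in WT libraries 1 to 3 and 94.0, 74.0 and 63.5 CPM in the KO libraries. After bacteria it was 197.4, 233.4 and 207.3 CPM in WT and 147.0, 191.4 and 124.0 CPM in KO. The difference of KO from WT was -0.44 log2 untreated (SE 0.17, edgeR adjusted p = 0.111) and -0.46 after bacteria (SE 0.17, edgeR adjusted p = 0.0806), so neither passed 0.05. Without the untreated KO library 1 the first was -0.66 (edgeR adjusted p = 0.0236), and without the treated KO library 2 the second was -0.65 (edgeR adjusted p = 0.0374). The sources used here do not state which part of the gene was deleted. A count over the whole gene can include reads from parts that remain, so these levels do not check the genotype labels. Slc29a3 rose with bacteria in both genotypes, by 1.03 log2 in WT (SE 0.17, edgeR adjusted p = 0.00135) and 1.00 in KO (SE 0.17, edgeR adjusted p = 0.00108). All 6 treated libraries lay above all 6 untreated ones.

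In WT cells, bacteria raised type I interferon, cytokine and chemokine genes together. Of 42 measured interferon response genes, 41 rose, with a median change of 3.66 log2. The antiviral effectors Ifit1 and Rsad2 rose 74.8-fold and 58.1-fold, from 22.2 ± 12.9 to 1663 ± 95.9 CPM and from 28.2 ± 14.0 to 1642 ± 194 CPM (mean ± SD, n = 3 here and throughout). Ifnb1, which encodes interferon β, had no count in any untreated WT library and 4.81 ± 2.40 CPM after bacteria, at least 87.4-fold higher against a floor of 3 counts over the group. Tnf rose from 38.6 ± 2.88 to 594 ± 172 CPM (3.94 log2, SE 0.26, edgeR adjusted p = 3.19e-06) and Cxcl10, a chemokine for activated T cells, from 18.1 ± 10.2 to 971 ± 160 CPM (5.74 log2, SE 0.46, edgeR adjusted p = 1e-05).

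Across the inflammatory cytokine list, 15 of 20 measured genes rose in WT cells and none fell (median 3.18 log2). Il27, Tnfsf15, Il10 and Il6 rose 91.6-fold, 35.4-fold, 17.1-fold and 11.9-fold. Il12b, the shared subunit of interleukins 12 and 23, rose 12.3-fold, to 1414 ± 963 CPM, and Il1b rose 3.66-fold. Among 15 chemokines 11 rose, including Cxcl11 (6.14 log2), Cxcl1 (5.22) and Ccl4 (4.33). Of 29 genes of NF-kB feedback and signalling 23 rose. These included Nfkbiz (3.61 log2), Socs3 (3.26) and the deubiquitinase gene Tnfaip3 (2.63, from 373 ± 12.8 to 2305 ± 305 CPM). In the list of DC maturation and migration, 14 of 23 genes rose and 1 fell. The costimulatory genes Tnfsf9 (3.43), Cd70 (3.03) and Cd40 (2.41, from 133 ± 9.17 to 710 ± 83.4 CPM) were among those that rose. These 5 lists passed the camera list test with either correlation, from an adjusted p of 1.59e-98 (interferon response) to 1e-16 (chemokines) with the preset correlation. With an estimated correlation their adjusted p ran from 8.95e-05 (cytokines) to 0.00989 (interferon response). Adjusted over the list alone, 41 interferon, 16 cytokine, 12 chemokine, 24 NF-kB and 15 maturation genes rose.

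**Figure D2:**
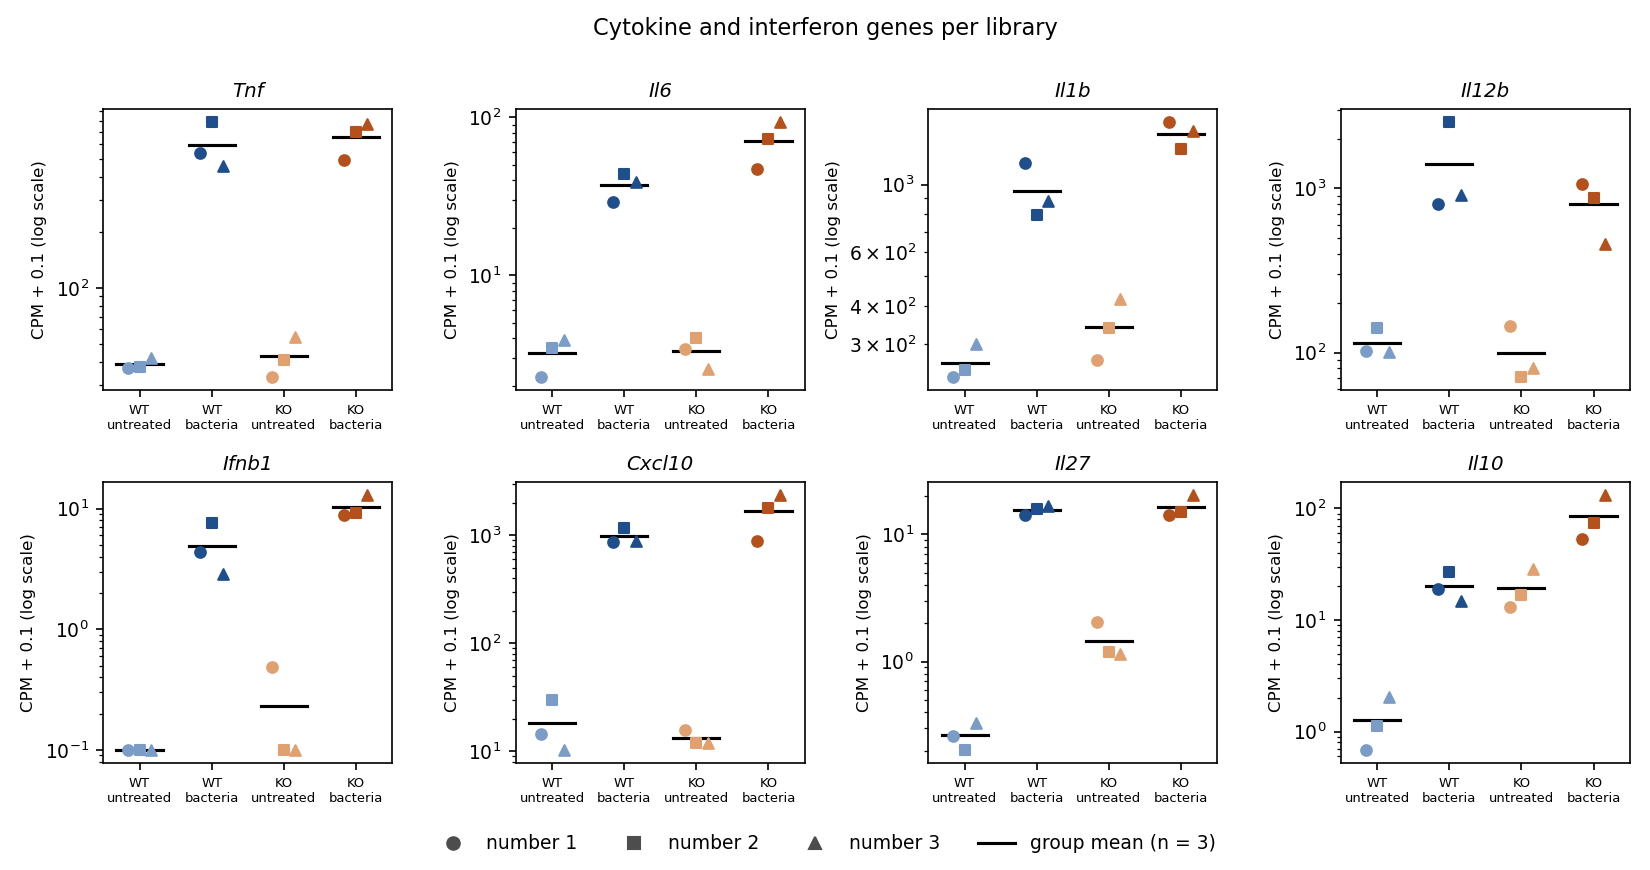
Level of 8 cytokine and interferon genes per library, as CPM plus 0.1 on log axes, in untreated and bacteria-treated WT and KO libraries; each point is a library, its shape the replicate number, and the line the group mean of 3. Tnf, Il6, Il1b, Il12b, Ifnb1, Cxcl10 and Il27 lie higher in treated than in untreated libraries of both genotypes, and Il10 in untreated KO libraries (19.4 CPM) lies near its level in treated WT libraries (20.2 CPM).

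Smaller list changes in WT cells passed the camera test only with the preset correlation. Of 30 genes for Toll-like receptors and adaptors, 11 rose and 3 fell (camera adjusted p = 0.0373; adjusted p = 0.271 with an estimated correlation). Myd88, the shared adaptor, rose 2.97-fold, Tlr7 3.04-fold and Cd14 3.22-fold. Of 19 genes for the inflammasome and pyroptosis, 7 rose (adjusted p = 0.00175; 0.262 with an estimated correlation), among them Nlrp3 (4.62-fold) and Casp4 (4.02-fold). Of 21 genes for MHC class I presentation, 9 rose, such as Tapbp (1.06 log2) and B2m (0.72), with adjusted p = 0.000586, and adjusted p = 0.563 with an estimated correlation. Only 2 of 14 MHC class II genes rose (adjusted p = 0.0365; 0.779 with an estimated correlation). With adjustment over each list alone, 13 Toll-like receptor genes rose and 4 fell, and 7 inflammasome, 10 class I and 2 class II genes rose. Scaled by library totals alone, the medians of the Toll-like receptor and inflammasome lists turned from 0.19 and 0.24 log2 to -0.13 and -0.09.

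Genes for autophagy and lysosomes moved in both directions in WT cells. Of 48 autophagy genes 3 rose and 9 fell (median -0.17 log2, camera adjusted p = 0.114, fry adjusted p = 0.00162). Ulk2, a kinase that starts autophagy, Calcoco1 and Rubcn, an inhibitor of autophagosome maturation, fell by 0.68, 0.92 and 1.08 on the log2 scale. Optn, an autophagy receptor, rose by 0.79. Of 69 lysosomal and TFEB target genes 13 rose and 5 fell (adjusted p = 0.487), with Cln3 (1.14) and the proton pump subunit gene Atp6v1a (0.92) among those that rose. Of 27 endolysosomal channels and transporters, 3 rose and 3 fell (adjusted p = 0.382). Mcoln1 was 33.8 ± 0.401 CPM untreated and 28.3 ± 3.48 CPM treated (-0.25 log2, SE 0.12, edgeR adjusted p = 0.157). Tfeb (-0.42), the transcription factor of lysosomal genes, its relative Tfe3 (-0.14), Map1lc3b (-0.19), Sqstm1 (0.43) and Slc15a4 (-0.12) did not pass. With the replicate number as a block within genotype Sqstm1 (0.42 log2, edgeR adjusted p = 0.00414) and Tfeb (-0.42, edgeR adjusted p = 0.0469) passed. Of 39 genes for nucleoside transport and purine or pyrimidine metabolism, 7 rose and 3 fell (adjusted p = 0.487). Nt5c3 (4.39-fold), Dck (3.56-fold), Pnp (2.64-fold) and the adenosine receptor gene Adora2a (2.25-fold) rose. The autophagy list gave 4 up and 9 down, the lysosome list 14 up and 5 down, the channel list 4 up and 3 down and the nucleoside list 7 up and 3 down when adjusted over the list alone.

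Other groups in WT cells showed single changes. The itaconate gene Acod1 rose 14.9-fold and the phagocyte oxidase gene Cybb 4.11-fold, while 26 of 33 genes of their list did not pass (adjusted p = 0.283). Hk2 and Ndrg1 of the glycolysis and hypoxia list rose 3.07-fold and 2.21-fold (6 of 27 rose, adjusted p = 0.0777). Of 28 immediate early and dissociation genes 8 rose and 1 fell (adjusted p = 0.0711; 0.0117 with the block within genotype), and of 27 genes of ER stress and amino acid response 4 rose (0.258), with Ppp1r15a 3-fold higher. Of 34 cell cycle genes 4 fell, such as Cdc20 (-1.54 log2), and Mki67 rose (1.52; adjusted p = 0.0677; 0.0122 with the block within genotype). Scd2 (-1.45), a desaturase, and Dhcr7 (-1.38), a cholesterol synthesis enzyme, fell, with list adjusted p of 0.221 for LXR and lipid handling (0.0157 with the block within genotype) and 0.446 for cholesterol synthesis. Ribosomal protein (0.083), mitochondrially encoded (0.0777), nuclear oxidative phosphorylation (0.429) and p53 target (0.982) lists did not pass. Among cell type markers, the cDC1 genes Btla (1.54) and Ifi205 (3.88) rose and Rab7b (-2.19) fell. The cDC1 (0.274), cDC2 (0.837), plasmacytoid DC (0.458), B (0.921), T (0.845), NK (0.673), macrophage (0.977), monocyte (0.985), neutrophil (0.982), erythroid (0.837), stroma (0.837) and sex-linked (0.985) lists did not pass. Among single genes with the widest changes were Trim30c, Gbp5 (44.6-fold higher), Chst2 (-3.45), Id3 (-2.71), Frat1 (-2.29), Tifab (-2.27) and Cx3cr1 (-2.25). Trim30c had 2 counts over the untreated WT libraries, and its ratio was 272 (95% counting interval 75 to 2250); its reads can be shared with near-identical family members.

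Over all 14293 tested genes, 1522 rose and 1154 fell in WT cells at an edgeR adjusted p under 0.05, of which 623 and 359 changed at least 2-fold. The groups did not overlap in 38.9% of genes, against 10% by chance for 3 against 3. Scaled by library totals alone, which moved the median of all genes to -0.354 log2, 799 rose and 4225 fell; with the replicate number as a block within genotype, 2377 rose and 2184 fell, and 2662 of the 2676 genes were shared with the fit without the block. Without the untreated WT library 2 or 3, 1509 and 1662 genes passed.

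KO cells also raised interferon, cytokine and chemokine genes with bacteria. Of the same 42 interferon response genes 41 rose (median 4.10 log2). Ifit1 rose 152-fold, to 2806 ± 1250 CPM, and Mx2 132-fold. Ifnb1 rose from 0.130 ± 0.225 to 10.2 ± 2.27 CPM. Tnf rose from 42.6 ± 10.6 to 651 ± 145 CPM (3.93 log2, SE 0.26, edgeR adjusted p = 1.47e-06), and Il6 from 3.24 ± 0.731 to 71.2 ± 23 CPM (4.46 log2, SE 0.30, edgeR adjusted p = 2.03e-06). Cxcl10 rose 128-fold, to 1668 ± 740 CPM, and Il12b 8.05-fold, to 798 ± 309 CPM.

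Of 20 inflammatory cytokine genes 19 rose in KO cells, with Tnfsf15 42.8-fold and Il1b 4.31-fold higher. Il23a had 3 counts over the untreated KO libraries, and its ratio was 27.0 (95% counting interval 8.84 to 134). Of 15 chemokines 11 rose, such as Cxcl11 (7.15 log2), Ccl4 (5.64), Cxcl2 (4.94) and Ccl5 (3.59). Of 29 NF-kB genes 26 rose, including Nfkbiz (2.95), Tnfaip3 (2.91) and Socs3 (2.83). Of 23 maturation genes 17 rose and 1 fell, with Tnfsf9 (3.96), Cd70 (3.05) and Cd40 (3.04) again among them. The 5 lists passed with either correlation, with camera adjusted p from 2.1e-98 (interferon response) to 5.88e-19 (chemokines), and from 9.23e-05 (cytokines) to 0.0146 (interferon response) with an estimated correlation. Over each list alone, 42 interferon, 19 cytokine, 12 chemokine, 27 NF-kB and 18 maturation genes rose.

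Further KO list changes passed the camera test only with the preset correlation. Of 21 genes for MHC class I presentation 11 rose, such as Tapbp (1.48 log2), its regulator gene Nlrc5 (1.12), Tap1 (0.95) and H2-T23 (0.94; camera adjusted p = 8.56e-06, and adjusted p = 0.327 with an estimated correlation). Of 19 inflammasome genes 6 rose, with Casp4 5.88-fold and Nlrp3 5.97-fold higher (0.000139; adjusted p = 0.163 with an estimated correlation). Of 28 immediate early genes 11 rose and 2 fell (0.000143; adjusted p = 0.337), with Egr1 (4.1-fold), Atf3 (4.24-fold) and Dusp2 (4.21-fold) among those that rose. Of 27 glycolysis and hypoxia genes 7 rose and 1 fell (0.0336; adjusted p = 0.931), with Hk2 5.23-fold and Pfkfb3 2.15-fold higher. The glycolysis list lost its call with the block within genotype (adjusted p = 0.0683). The ribosomal protein list passed with 1 of 60 genes up (0.00644; adjusted p = 0.944). When p was adjusted within each list, 13 class I, 6 inflammasome, 11 immediate early, 8 glycolysis and 0 ribosomal genes rose. Scaled by library totals alone, the inflammasome and ribosomal medians turned from 0.20 and 0.19 log2 to -0.13 each.

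Autophagy, lysosome and channel genes of KO cells moved both ways. Of 48 autophagy genes 3 rose and 12 fell (median -0.2 log2, camera adjusted p = 0.0719, fry adjusted p = 0.000256). Optn rose (1.17 log2), and Atg4c (-1.27), Rubcn (-1.26) and Ulk2 (-0.90) fell. Tfeb fell by 1.03 on the log2 scale, from 91.1 ± 13.4 to 44.7 ± 13.4 CPM (SE 0.19, edgeR adjusted p = 0.00185). In the lysosome list 8 rose and 9 fell (adjusted p = 0.973; median and mean of opposite sign, 0.01 and -0.04). The heparan sulfatase gene Sgsh (-2.55) and the sphingomyelinase gene Smpd1 (-1.04) fell, while Atp6v0a1 (1.51) rose. Of 27 channels and transporters 5 rose, such as Mcoln2 (1.58), and 9 fell, such as the endolysosomal channel gene Tpcn1 (-1.10; list adjusted p = 0.206). Mcoln1 was 32.2 ± 1.13 CPM untreated and 25.5 ± 2.95 CPM treated (-0.34 log2, SE 0.12, edgeR adjusted p = 0.0586). Sqstm1 (0.56), Tfe3 (-0.10) and Map1lc3b (-0.25) did not pass. With the block within genotype Mcoln1 (-0.35, edgeR adjusted p = 0.0324), Sqstm1 (0.54, 0.000538) and Map1lc3b (-0.25, 0.0376) passed. In the nucleoside list Nt5c3 (4.51-fold), Dck (3.63-fold), Pnp (2.93-fold) and Adora2a (2.76-fold) rose again (7 up, 4 down; adjusted p = 0.701). The Toll-like receptor (13 up, 4 down; 0.0719), class II (0.0719), phagocyte (0.141), ER stress (0.204), oxidative phosphorylation (0.96), mitochondrial (0.714), cholesterol (0.722), lipid (0.624), cell cycle (0.0719) and p53 (0.517) lists and all cell type lists (from 0.47 to 0.984) did not pass the camera test in KO cells. The class II and cell cycle lists passed with the block within genotype (camera adjusted p = 0.0168 and 0.013). Other wide changes were Il33 (162-fold higher), Gbp5 (66.4-fold higher), B3gnt8 (-3.96), Arl11 (-3.04) and Smad6 (-2.84). Adjusted over the list alone, 3 autophagy genes rose and 13 fell, 8 lysosome genes rose and 9 fell, 5 channel genes rose and 12 fell, and 7 nucleoside genes rose and 5 fell.

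In KO cells 1654 genes rose and 1638 fell at an edgeR adjusted p under 0.05, of which 821 and 552 changed at least 2-fold, and 40.3% of genes did not overlap between the groups against 10% by chance. The responses of the genotypes shared 1189 rising and 779 falling genes, where independent lists would share 176.1 and 132.3; across genes, which are not independent replicates, the fold changes correlated with r = 0.745 and rho = 0.73. Scaled by library totals alone, which moved the median to -0.381 log2, 1030 rose and 4691 fell; with the block within genotype 2369 rose and 2617 fell, 3267 of the 3292 genes being shared. Without the untreated KO library 2 or 3, 2132 and 2185 genes passed.

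Untreated KO cells differed from untreated WT cells in genes of several myeloid and erythroid cell types. Of 15 measured erythroid and platelet genes 11 were higher in KO. The globin gene Hba-a1 rose from 2.38 ± 1.43 CPM in WT to 1063 ± 410 CPM in KO and Hbb-bs from 3.64 ± 1.91 to 1312 ± 604 CPM, with the near-identical copies Hba-a2 and Hbb-bt uncertain since reads can be split between them. Of 14 neutrophil genes 12 were higher, of 20 macrophage genes 14, and of 15 monocyte genes 9 (1 was lower). The macrophage complement genes C1qb and C1qc were 35.6-fold and 46.4-fold higher, and the monocyte gene Cd300e 34.9-fold, at 5.92 ± 2.51 CPM in WT and 207 ± 100 CPM in KO. The erythroid list passed with either correlation (camera adjusted p = 1.91e-24, and 0.000123 with an estimated correlation). The neutrophil (6.69e-09), macrophage (8.39e-15) and monocyte (4.69e-06) lists did so only with the preset value, and with an estimated correlation their adjusted p was 0.233, 0.168 and 0.061. With adjustment over each list alone, 12 erythroid, 14 neutrophil, 14 macrophage and 10 monocyte genes were higher and 1 monocyte gene lower.

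**Figure D3:**
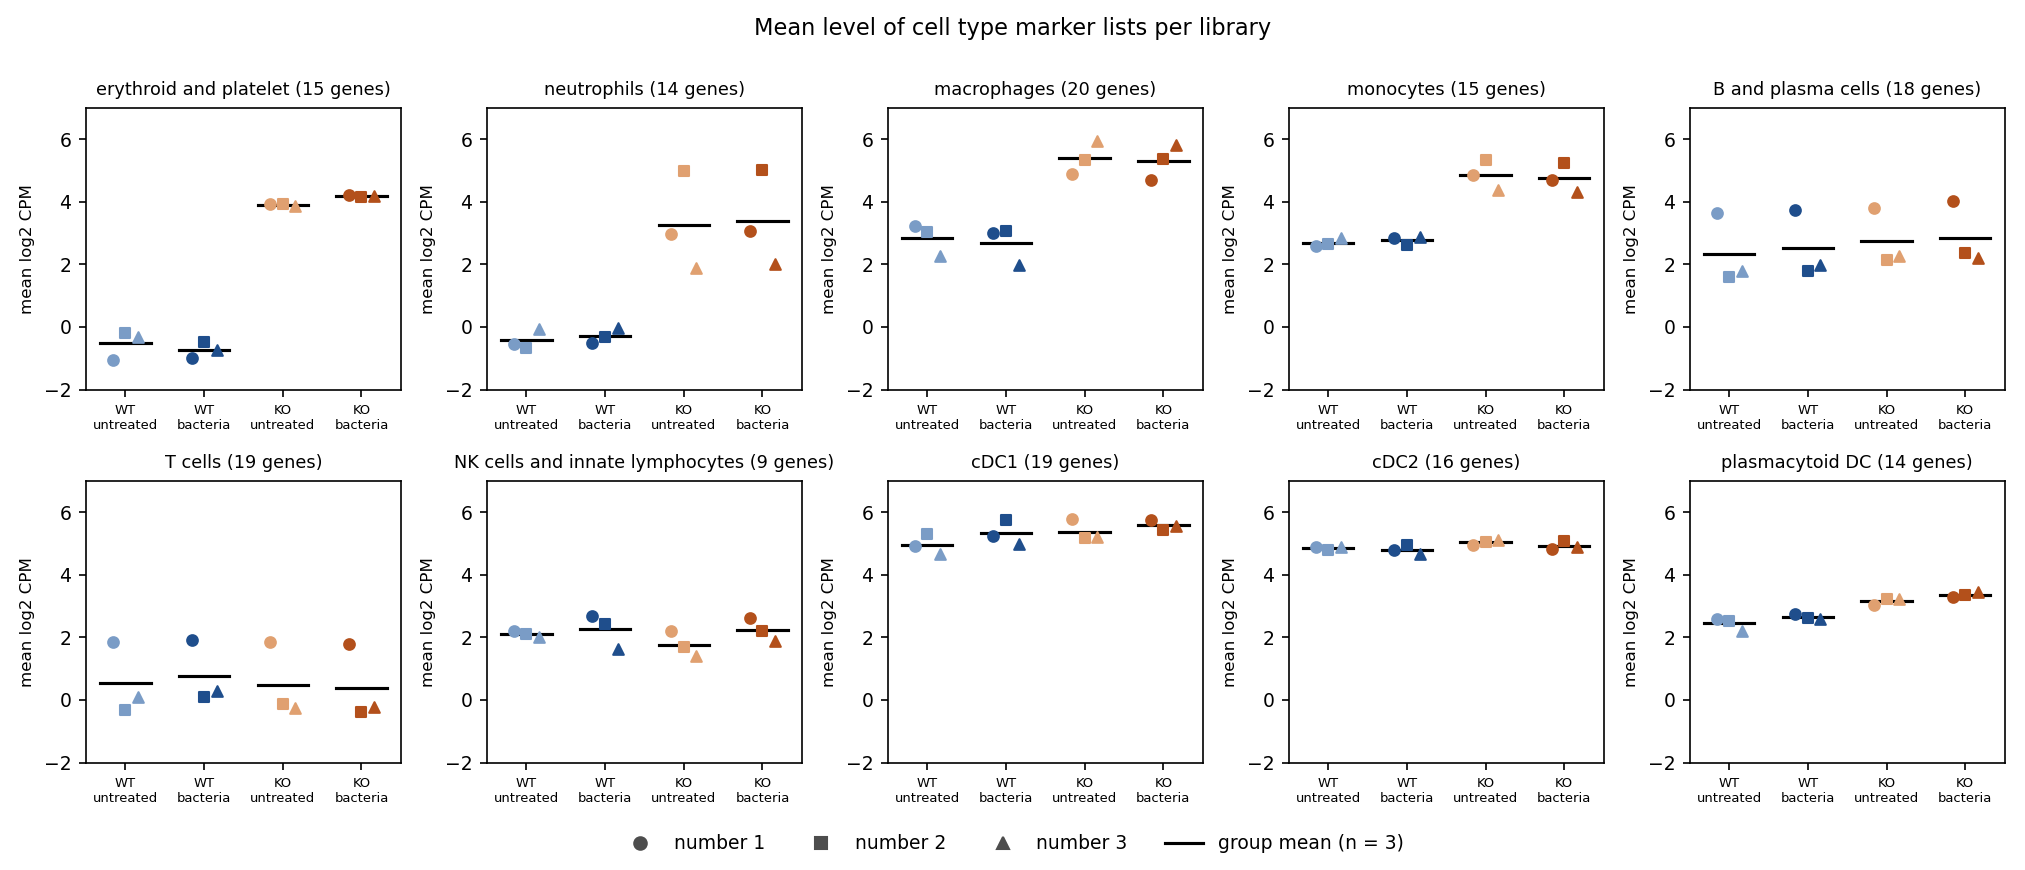
Mean log2 CPM of 10 cell type marker lists per library, in untreated and bacteria-treated WT and KO libraries; each point is a library, its shape the replicate number, and the line the group mean of 3. Erythroid, neutrophil, macrophage and monocyte lists lie higher in all 6 KO libraries than in all 6 WT libraries, while B and T cell lists are highest in the libraries numbered 1.

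Markers of the DC types differed less between untreated genotypes, and globin genes made up 0.3% ± 0.125 of counts in KO against 0.001% ± 0.001 in WT. In the cDC1 list 3 of 19 genes were higher (camera adjusted p = 0.127). In the cDC2 list 3 of 16 were higher, such as Cx3cr1 (3.67 log2), Itgam (2.46) and Sirpa (1.43), and 3 were lower, such as Dtx1 (-1.34; adjusted p = 0.871; median -0.27 and mean 0.22). In the plasmacytoid DC list 4 of 14 were higher, such as Cox6a2 (4.64) and Lair1 (2.77; adjusted p = 0.108). Of 5 stroma and endothelium genes 2 were higher, with Pecam1 at 9.25 ± 3.78 and 149 ± 52.6 CPM (0.00119; adjusted p = 0.184 with an estimated correlation). B cell (0.499), T cell (0.368), NK cell (0.288) and sex-linked (0.784) lists did not pass. Over each list alone, 5 cDC1, 4 cDC2, 4 plasmacytoid and 2 stroma genes were higher and 5 cDC2 genes lower.

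Part of the genes of lysosomes, phagocytosis and lipid handling and most cell cycle genes were higher in untreated KO cells, in the same libraries in which macrophage, neutrophil and erythroid markers were higher (list medians 2.66, 4.81 and 5.96 log2). Of 69 lysosomal genes 28 were higher and 1 lower. These included the progranulin gene Grn (2.63 log2, from 69.5 ± 13.3 to 430 ± 168 CPM) and the protease genes Ctsl (2.39) and Ctsf (3.74). Of 33 phagocyte genes 14 were higher and 2 lower, such as Fcgr4 (7.00), Fcgr1 (5.63) and Mertk (4.62). Of 20 genes for LXR and lipid handling 7 were higher, such as the LXR gene Nr1h3 (4.08), Pltp (4.48) and the sterol exporter Abcg1 (3.44), and 2 were lower. Of 34 cell cycle genes 24 were higher, such as E2f1 (1.71) and Rrm2 (1.48). The 4 lists had camera adjusted p of 1.95e-07, 2.62e-05, 0.0023 and 5.9e-17, and adjusted p = 0.326, 0.168, 0.267 and 0.184 with an estimated correlation. When p was adjusted within each list, 35 lysosomal, 18 phagocyte, 9 lipid and 32 cell cycle genes were higher, and 2, 3, 3 and 0 lower.

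Of 39 genes for nucleoside transport and metabolism, 7 were higher and 1 was lower in untreated KO cells, in libraries that also differed in macrophage markers (camera adjusted p = 0.0176; adjusted p = 0.184 with an estimated correlation). Slc29a1, the equilibrative transporter of the plasma membrane, was 3.92-fold higher (9.63 ± 1.93 and 37.7 ± 10.9 CPM, 1.97 log2, SE 0.25, edgeR adjusted p = 0.000638). The guanine deaminase gene Gda was 10.2-fold higher (1.72 ± 0.358 and 17.5 ± 5.20 CPM), and the lysosomal nuclease gene Pld3 5.96-fold. Of 27 endolysosomal channels and transporters 7 were higher, such as the metal transporter gene Slc11a1 (2.23) and the amino acid transporter gene Slc36a1 (1.41), and 1 was lower (0.0254; adjusted p = 0.46 with an estimated correlation). Mcoln1 was 33.8 ± 0.401 CPM in WT and 32.2 ± 1.13 CPM in KO (-0.07 log2, SE 0.12, edgeR adjusted p = 0.785). Of 48 autophagy genes 5 were higher and 1 was lower (adjusted p = 0.498). Map1lc3b (0.00), Tfeb (-0.07), Tfe3 (-0.18), Slc15a4 (0.18) and Sqstm1 (-0.70, SE 0.22, edgeR adjusted p = 0.0547) did not pass. Adjusted over the list alone, 8 nucleoside, 10 channel and 5 autophagy genes were higher and 1, 2 and 1 lower.

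Some chemokine, maturation, immediate early, ER stress and cholesterol genes were lower in untreated KO cells, with the marker differences named above in the same libraries. Of 15 chemokines 6 were lower, such as Ccl22 (663 ± 206 CPM in WT and 175 ± 53.1 CPM in KO), Ccl9 (-1.67 log2) and Ccl5 (-1.30; camera adjusted p = 0.000167, and adjusted p = 0.061 with an estimated correlation). Of 23 maturation genes 11 were lower, such as the costimulatory gene Tnfsf4 (-1.09; 6.69e-09; adjusted p = 0.061). Of 28 immediate early genes 10 were lower, such as Egr2 (-1.35), Egr3 (-1.23) and Dusp1 (-0.81; 2.32e-05; adjusted p = 0.233). Of 27 genes of ER stress and amino acid response 5 were lower, such as the cystine transporter gene Slc7a11 (-1.31), and 2 were higher, such as Cebpb (2.26; 0.00058; adjusted p = 0.482). Of 21 cholesterol synthesis genes 5 were lower (list median -0.84; 6.69e-09; adjusted p = 0.326). Their mean level was 6.14 log2 CPM in the untreated KO library 1, 5.50 and 5.28 in KO libraries 2 and 3, and 6.24 to 6.59 in WT. No ribosomal protein gene passed, with a list median of -0.14 (0.000759; adjusted p = 0.632). With adjustment over each list alone, 6 chemokine, 14 maturation, 12 immediate early, 6 ER stress and 15 cholesterol genes were lower, 0 ribosomal genes passed, and 1 maturation, 2 immediate early and 2 ER stress genes were higher.

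Cytokine and receptor genes at rest went both ways, beside higher macrophage and monocyte markers. Il10, an anti-inflammatory cytokine, was 16.5-fold higher in untreated KO cells (1.18 ± 0.685 and 19.4 ± 8.33 CPM, 4.05 log2, SE 0.50, edgeR adjusted p = 0.000594), and Il27 8.09-fold (0.163 ± 0.0622 and 1.36 ± 0.509 CPM). Tnf (0.14), Il6 (0.05), Il1b (0.39), Il12b (-0.21), Cxcl10 (-0.48) and Myd88 (0.31) did not pass. Tlr8 (5.11), Cd14 (2.05) and Tlr4 (2.43) were higher, and Tlr4 missed the threshold in 1 alternative. Nlrp3 (-1.01) and Mefv (-1.08) were lower, while the inflammasome adaptor gene Pycard was higher (3.15). The interferon genes Iigp1 (3.03), Gbp3 (1.94) and Igtp (1.79) and the NF-kB genes Ikbke (4.01), Irak3 (3.95) and Socs3 (2.43) were higher, while the NF-kB genes Tnip3 (-1.01) and Tnfaip2 (-0.92) were lower. Of 29 NF-kB genes 5 were higher and 6 lower, and 6 and 15 adjusted over the list alone. The cytokine (2 up, 1 down; 0.904), interferon (5 up; 0.288), NF-kB (0.12), Toll-like receptor (6 up, 2 down; 0.572), inflammasome (2 up, 3 down; 0.531), class I (1 down; 0.186), class II (3 up, 2 down; 0.319), glycolysis (0.504), oxidative phosphorylation (0.319), mitochondrial (0.174) and p53 (0.0973) lists did not pass the camera test. Medians and means differed in sign in the cytokine (-0.26 and 0.07), NF-kB (-0.29 and 0.13) and class II (-0.12 and 0.04) lists, and the inflammasome list tested downward with a median of 0.13.

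Single genes with the widest untreated differences included Apol11b, absent from all WT libraries and at 13.2 ± 5.44 CPM in KO, at least 240-fold higher over a floor of 3 counts. The complement gene C4b had 1 count over the WT libraries and a ratio of 673 (95% counting interval 120 to 26600), and the iodide transporter gene Slc5a5 rose from 0.129 ± 0.117 to 82.2 ± 56.7 CPM. The elastase gene Mmp12 was lower in KO (88.6 ± 9.93 and 9.49 ± 1.08 CPM, -3.22 log2, SE 0.16, edgeR adjusted p = 1.53e-06), as were H2-M2 (-3.23) and Apol7c (-3.02). Reads of Apol11b, Apol7c and H2-M2 can be shared with near-identical family members. In all, 1358 genes were higher and 494 lower in untreated KO cells, 954 and 130 of them by at least 2-fold, and 37.4% of genes did not overlap between groups against 10% by chance. Scaled by library totals alone, 1669 were higher and 308 lower. Without the untreated WT library 2 or 3, or the untreated KO library 2 or 3, 1126, 863, 1056 and 957 genes passed.

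**Figure D4:**
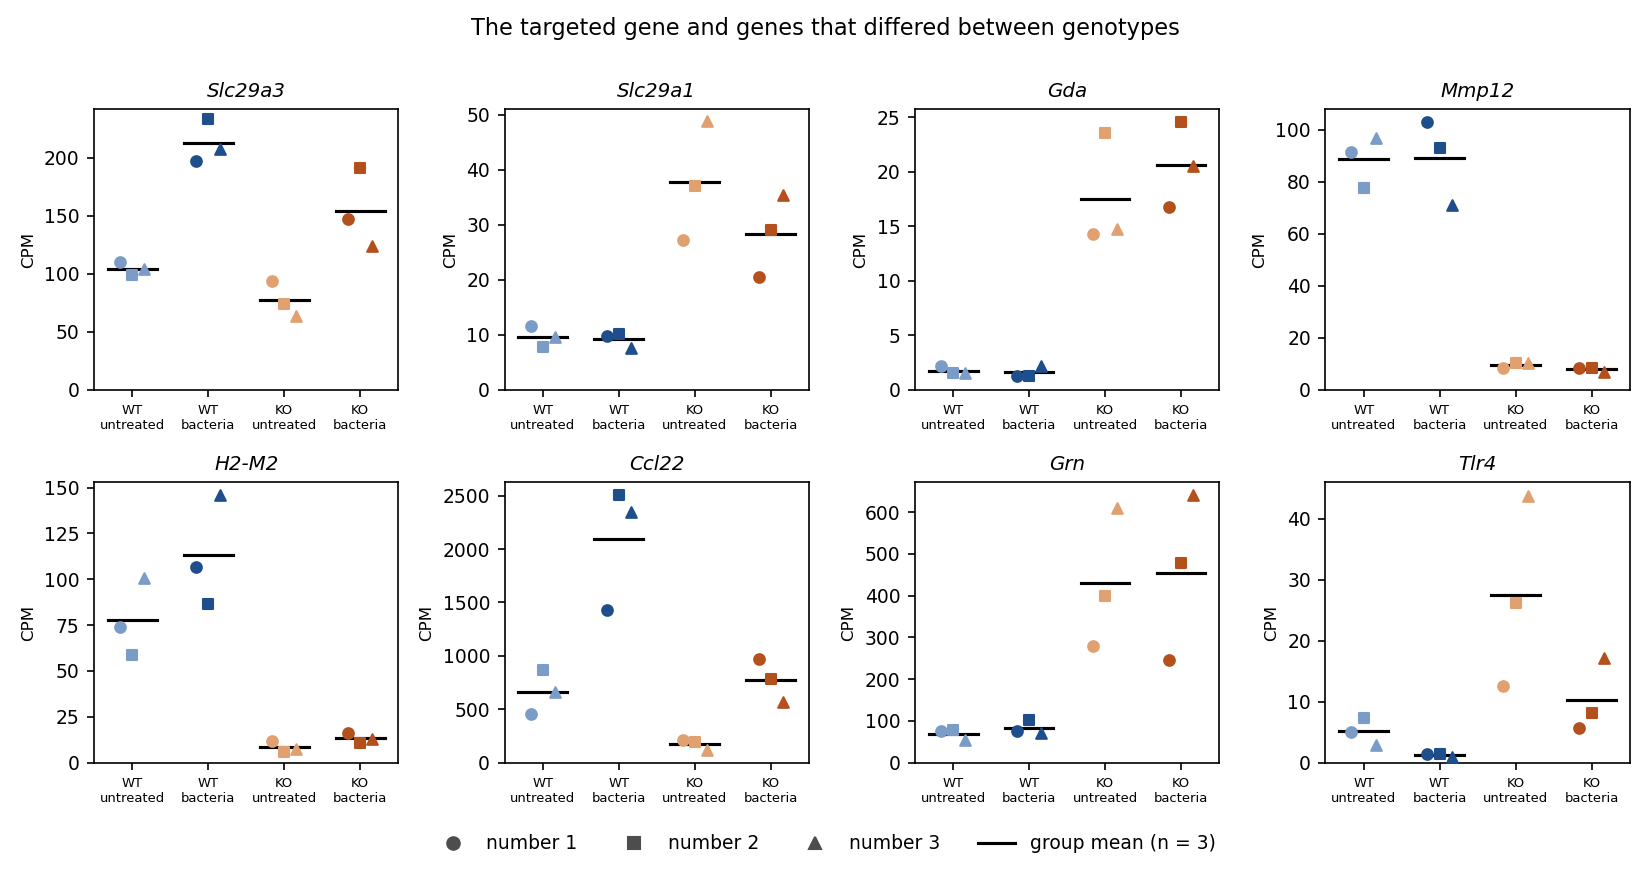
CPM of Slc29a3 and 7 genes that differed between genotypes, per library in untreated and bacteria-treated WT and KO cells; each point is a library, its shape the replicate number, and the line the group mean of 3. Mmp12 and H2-M2 lie lower, and Slc29a1, Gda and Grn higher, in all 6 KO libraries than in all 6 WT libraries, while Slc29a3 remains at 63.5 CPM or above in KO.

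After bacteria, KO cells still carried higher erythroid, neutrophil, macrophage and monocyte markers than WT cells. Of 15 erythroid and platelet genes 12 were higher, of 14 neutrophil genes 10, of 20 macrophage genes 14 and of 15 monocyte genes 6, with 1 monocyte gene lower. Hba-a1 was at 2.46 ± 0.926 CPM in WT and 1198 ± 624 CPM in KO, the neutrophil collagenase gene Mmp8 at 0.153 ± 0.174 and 7.47 ± 8.11 CPM, and the macrophage gene Cd5l at 1.15 ± 0.922 and 89.2 ± 43.4 CPM. The erythroid list passed with either correlation (camera adjusted p = 7.26e-29; 0.000111 with an estimated one). The neutrophil (1.55e-08), macrophage (3.26e-14) and monocyte (2.9e-05) lists had adjusted p = 0.286, 0.261 and 0.199 with an estimated correlation. Over each list alone, 12 erythroid, 14 neutrophil, 15 macrophage and 9 monocyte genes were higher and 1 monocyte gene lower.

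Innate immune genes after bacteria differed in a few members, beside globin counts of 0.283% ± 0.146 in KO against 0.001% ± 0.001 in WT. Of 42 interferon genes 10 were higher in KO, such as Iigp1 (4.20 log2) and Gbp3 (1.87; camera adjusted p = 1.42e-06, and adjusted p = 0.566 with an estimated correlation), and 12 adjusted over the list alone. The mean level of the list was 7.13 log2 CPM in the treated KO library 1, 8.03 and 8.27 in KO libraries 2 and 3, and 6.89 to 7.13 in WT. Of 20 cytokines 4 were higher, with Il10 at 20.2 ± 6.13 and 86.3 ± 40.4 CPM (2.10 log2, SE 0.41, edgeR adjusted p = 0.00625), Il6 0.94 log2 higher (edgeR adjusted p = 0.0312) and Il1b 0.63 (0.0394; list adjusted p = 0.22). Il6 lost its call in 4 alternatives and Il1b in 7. Tnf (0.13), Il12b (-0.82), Ifnb1 (1.09), Cxcl10 (0.78) and Myd88 (0.39) did not pass. Of 15 chemokines 4 were lower, such as Ccl9 (-1.46; list adjusted p = 0.165). Of 23 maturation genes 5 were lower, such as Cd83 (-0.99) and Tnfsf4 (-0.81), and 1 was higher (0.000389; adjusted p = 0.262 with an estimated correlation). Of 30 Toll-like receptor genes 5 were higher, such as Tlr2 (1.72), Tlr4 (3.11) and Tlr8 (4.74), and 3 lower, such as Cd180 (-0.80), and 5 and 4 adjusted over the list alone. The lists for NF-kB (4 up, 1 down; 0.722), Toll-like receptors (0.722), the inflammasome (3 up, 3 down; 0.7), class I (1 up; 0.925) and class II (1 up, 3 down; 0.223) did not pass. When p was adjusted within each list, 4 cytokines and 1 maturation gene were higher, and 4 chemokines and 8 maturation genes lower.

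Part of the lysosomal, phagocyte, lipid and nucleoside genes and most cell cycle genes were again higher in KO cells after bacteria, in the libraries with higher macrophage markers (list median 2.36 log2). Of 69 lysosomal genes 21 were higher and 1 lower, with Grn at 83.8 ± 16.8 and 455 ± 199 CPM (camera adjusted p = 0.000147; adjusted p = 0.544 with an estimated correlation). The lower gene was Tfeb, at 71.7 ± 4.61 and 44.7 ± 13.4 CPM (-0.68 log2, SE 0.19, edgeR adjusted p = 0.0294), a call lost in 4 alternatives. Of 33 phagocyte genes 17 were higher and 2 lower, such as Hp (4.98; 1.47e-06; adjusted p = 0.199). Of 20 lipid genes 10 were higher, such as Plin2 (3.20) and Fabp4 (4.15), and 3 lower (0.000311; adjusted p = 0.262). Of 39 nucleoside genes 12 were higher, such as Gda (12.8-fold), Slc28a2 (6.7-fold) and Slc29a1 (3.1-fold), and 2 lower (0.0409; adjusted p = 0.286). Of 34 cell cycle genes 23 were higher, such as Rrm2 (1.86; 2.13e-15; adjusted p = 0.262). Of 48 autophagy genes 2 were higher, such as Wipi1 (2.04), and 4 lower, such as Gabarapl1 (-0.55; list adjusted p = 0.251). Mcoln1 was 28.3 ± 3.48 and 25.5 ± 2.95 CPM (-0.15 log2, SE 0.12, edgeR adjusted p = 0.431). Tfe3 (-0.14), Map1lc3b (-0.07), Sqstm1 (-0.58) and Slc15a4 (-0.17) did not pass, and 6 channel genes were higher and 1 lower (0.149). Adjusted over the list alone, 25 lysosomal, 20 phagocyte, 10 lipid, 14 nucleoside, 30 cell cycle, 2 autophagy and 7 channel genes were higher, and 2, 3, 3, 4, 0, 4 and 2 lower.

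Metabolic and stress genes lower in treated KO cells included 7 of 27 ER stress genes, such as Slc7a11 (-1.13 log2) and Sesn2 (-0.70), with 1 higher, the transcription factor gene Cebpb (3.20; camera adjusted p = 0.00275, and adjusted p = 0.566 with an estimated correlation). In the same libraries erythroid, neutrophil, macrophage and monocyte markers were higher (list medians 5.64, 4.47, 2.36 and 1.49 log2). Of 21 cholesterol synthesis genes 5 were lower (camera adjusted p = 2.43e-07, and 0.43 with an estimated correlation). Their mean level was 5.99, 5.34 and 5.10 log2 CPM in KO libraries 1 to 3 and 6.15 to 6.43 in WT. Of 12 mitochondrially encoded genes 3 were lower (camera adjusted p = 0.00299, and 0.566 with an estimated correlation). The mean level of this list was 6.82, 6.53 and 6.97 log2 CPM in KO libraries 1 to 3 and 7.04, 7.43 and 6.93 in WT libraries 1 to 3. Of 42 oxidative phosphorylation genes 2 were higher (0.0159; adjusted p = 0.58), and of 5 stroma genes 2, Kdr (2.12) and Pecam1 (3.40; 0.00204; adjusted p = 0.262). With adjustment over each list alone, 9 ER stress, 16 cholesterol and 3 mitochondrial genes were lower, and 1 ER stress, 0 oxidative phosphorylation and 3 stroma genes higher. The immediate early (0.149), glycolysis (0.183), ribosomal (0.0849), p53 (0.657), cDC1 (0.373), cDC2 (0.884), plasmacytoid DC (0.134), B (0.364), T (0.223), NK (0.722) and sex-linked (0.884) lists did not pass. Apol11b was again without a count in WT and at least 249-fold higher in KO, at 14.1 ± 3.77 CPM; Aldh1a1 and the erythroid genes Rhag and Trim10 were at least 106-fold, 138-fold and 128-fold higher. Mmp12 (-3.50), Cd207 (-3.23), the gene of langerin, H2-M2 (-3.11), Dcstamp (-1.97) and Adgrl3 (-1.92) were lower.

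After bacteria 1317 genes were higher and 699 lower in KO cells at an edgeR adjusted p under 0.05, 941 and 152 of them by at least 2-fold, and 28.8% of genes did not overlap against 10% by chance. The untreated and treated genotype differences shared 930 higher and 260 lower genes, where independent lists would share 125.1 and 24.2 (r = 0.835 and rho = 0.668 across genes). Scaled by library totals alone, 1631 were higher and 312 lower after bacteria. Libraries of the same number resembled each other across treatment, so these differences are not independent. Without the treated WT library 3 or the treated KO library 2 or 3, 1087, 1028 and 1030 genes passed, and 1074 with only the groups compared in the fit.

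**Figure D5:**
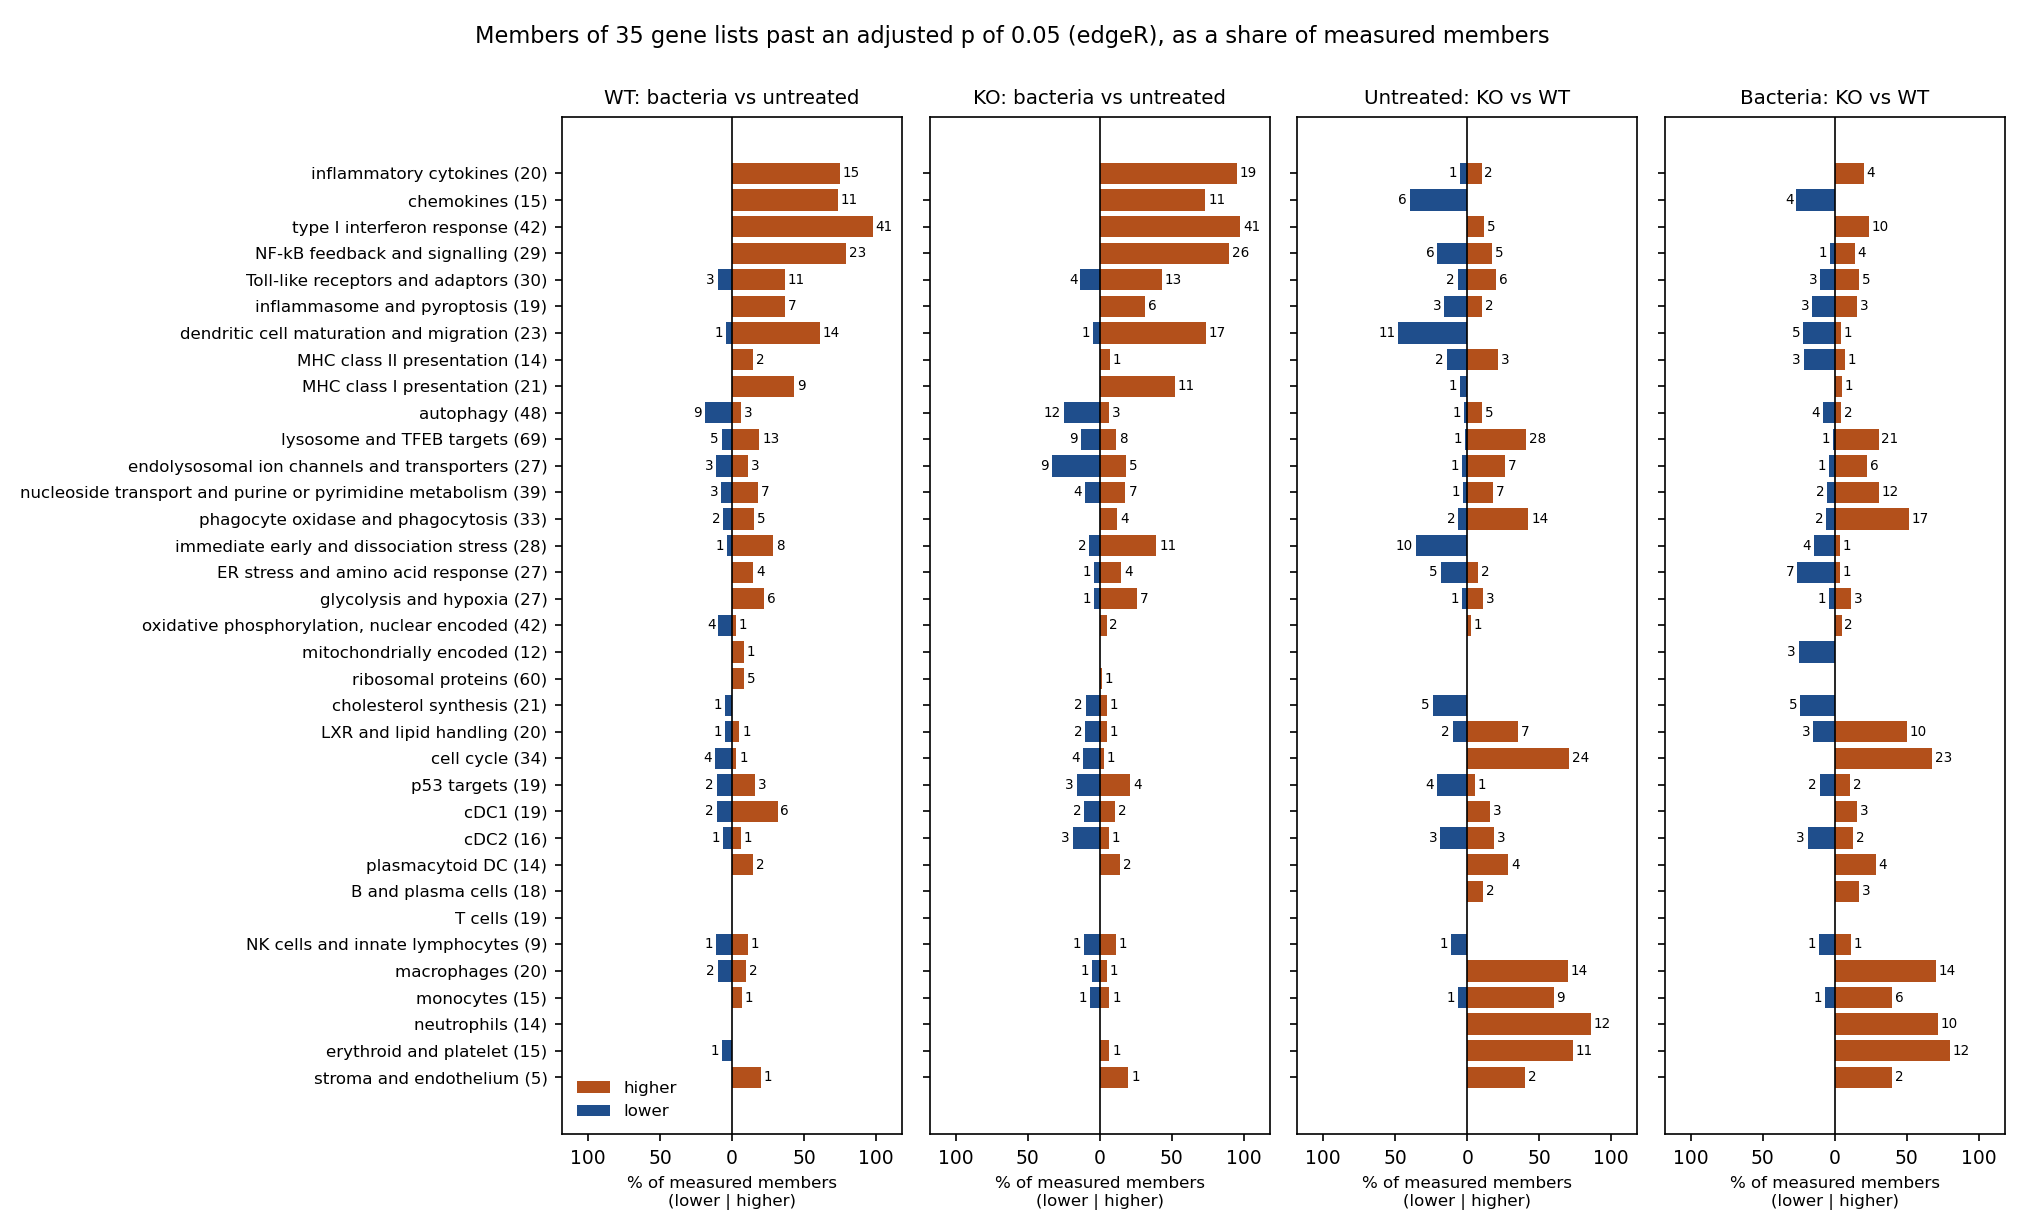
Share of measured members of 35 gene lists that passed an edgeR adjusted p of 0.05, higher to the right and lower to the left, with counts beside the bars, in the 4 comparisons of groups; the number measured stands after each list name. Interferon response bars reach 41 of 42 genes in both responses to bacteria, and erythroid, neutrophil, macrophage and cell cycle bars are long between genotypes.

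A higher share of calls in the flanking region of Slc29a3 was not shown, and is not excluded. Of 235 tested genes within 20 Mb, 36 (15.3%) differed between untreated genotypes against 13% of all genes (odds ratio 1.22, two-sided Fisher's exact p = 0.281). After bacteria 34 (14.5%) differed against 14.1% (odds ratio 1.03, Fisher's exact p = 0.85). Within 1 Mb, a window chosen after the data were seen, 5 of 21 genes differed untreated (odds ratio 2.1, Fisher's exact p = 0.18) and 4 of 21 treated (1.43, Fisher's exact p = 0.526), all higher in KO. Among them were Pcbd1 (4.95 log2 untreated, 6.35 treated), Unc5b (3.15 and 3.31) and Psap of the lysosome list (0.88 and 0.86). A comparison of shares does not weigh the size of such differences.

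Whether the response to bacteria differed by genotype was tested as the interaction, and no single gene passed in edgeR. At an unadjusted p under 0.05 there were 608 genes, and DESeq2 called 6. Il27 had the smallest adjusted p (0.383), with a KO response 2.93 log2 below that of WT (SE 0.45), and passed with the block within genotype (edgeR adjusted p = 0.0246). Its treated levels were 15.4 ± 1.31 CPM in WT and 16.4 ± 3.34 CPM in KO. The responses of Tnf (-0.01), Il6 (0.89), Il1b (0.24), Il12b (-0.62), Cxcl10 (1.26), Myd88 (0.08), Tlr4 (0.69), Tfeb (-0.61), Tfe3 (0.04), Mcoln1 (-0.09), Map1lc3b (-0.06), Sqstm1 (0.13), Slc15a4 (-0.35) and Slc29a3 (-0.03) differed by these log2 values without passing. Genes induced in both genotypes on average (861) had a median KO minus WT response of 0.249 log2 (two-sided exact permutation p = 0.165 over 400 arrangements, smallest possible 0.005). Genes lowered by bacteria (621) had -0.105 (exact permutation p = 0.58). Without the untreated WT library 3 or the untreated KO library 1 the induced value was 0.306 (exact permutation p = 0.045) and 0.342 (p = 0.02), and without the treated KO library 1 it was 0.423 (p = 0.065), with libraries reassigned singly. Reassignment within treatment carries the genotype difference into arrangements with unequal numbers of KO libraries, so these p-values are not exact for response size. With same-numbered libraries of a genotype kept together, which avoids this, the permutation p over all libraries was 0.3 for induced and 0.6 for lowered genes (20 arrangements, smallest possible 0.1).

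With the replicate number as a block within genotype, 41 genes passed the interaction in edgeR. Spic, a transcription factor gene of red pulp macrophages, changed by -0.39 in WT and 1.17 in KO (1.56, SE 0.15, edgeR adjusted p = 0.000259), and Egr1 by 0.38 and 1.98. Slc40a1, the iron exporter gene, changed by -2.08 and -0.82, Adgre1, which encodes the macrophage marker F4/80, by 1.07 and 0.07, and Abcg1 by 0.07 and -1.03. The macrophage list also differed between the genotypes at rest, though its members did so unevenly. Untreated Adgre1 was at 22.8 ± 9.46 CPM in WT and 136 ± 43.6 CPM in KO, and Spic at 115 ± 20.9 and 151 ± 56.6 CPM. Without the untreated KO library 1 or the treated KO library 1, 2 and 8 genes passed in the fit without the block.

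Among lists, 6 of 36 passed the camera test of the interaction with the preset correlation and none with an estimated one. The median KO minus WT response was above 0 in chemokines (0.82 log2, adjusted p = 0.00195), interferon response (0.59, 4.08e-07), NF-kB (0.15, 0.00516), maturation (0.22, 0.00525) and immediate early genes (0.17, 0.000486), and below 0 in mitochondrially encoded genes (-0.19, 0.0472). No member of these lists passed over all genes. The list median of KO minus WT was -0.48 untreated and -0.05 treated in chemokines, and -0.29 and -0.11 in NF-kB (means 0.13 and 0.27). For maturation it was -0.53 and -0.24, for immediate early genes -0.32 and -0.14, and for interferon response 0.13 and 0.71. Of these lists only interferon response thus had a treated median above 0. Libraries numbered 1 lay near or below 0 in the 5 lists with positive medians. By number 1, 2 and 3 the difference of mean responses was 0.00, 0.92 and 0.49 for interferon response, and -0.22, 0.68 and 0.92 for chemokines. It was 0.00, 0.22 and 0.22 for NF-kB, 0.01, 0.18 and 0.34 for maturation and -0.01, 0.47 and 0.32 for immediate early genes. In mitochondrially encoded genes number 2 alone was below 0 (0.14, -1.01 and 0.16). With an estimated correlation the adjusted p of the 6 lists was 0.228, 0.982, 0.565, 0.565, 0.565 and 0.982. The mitochondrial list lost its call with the block within genotype (adjusted p = 0.0862) and the interferon list without the untreated WT library 2 (median 0.28). The maturation list lost it without the untreated WT library 3, the treated WT library 1 or the untreated KO library 3. With each library left out in turn, from 4 to 12 lists passed, so calls other than those named here changed too. Over each list alone, 1 NF-kB gene was higher and no gene of the other 5 lists passed.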

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

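The tests of other cells, of preparation, of a partial transcript, of an exchange of whole groups and of a cell mixture were chosen after the results were seen, while the other splits of the libraries and the test of swapped labels were planned. Responses of 6 lists were set apart because they differed between genotypes with the preset correlation: chemokines (median KO minus WT response 0.82 log2), interferon response (0.59), NF-kB (0.15), maturation (0.22), immediate early genes (0.17) and mitochondrially encoded genes (-0.19). For the same reason the 41 genes of the interaction with the replicate block within genotype were set apart.

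Other splits of the same libraries show what the counts of calls can bear. The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, so the share of splits cannot go under 0.1 and chance cannot be excluded. The labelled split alone (1 of 10) gave as many genes in the WT response (2676, highest other split 0), the KO response (3292, highest other 0), the untreated genotype difference (1852, highest other 0) and the treated one (2016, highest other 6). In 4 of the 10 splits every same-numbered pair was parted, and the highest count of genes among those other than the labels was 0. Lists behaved otherwise: 8 of 10 splits gave at least the 9 lists of the WT response (highest other 16), 8 of 10 the 10 lists of the KO response (22), 3 of 10 the 17 lists of the untreated genotype difference (20) and 1 of 10 the 16 lists of the treated one (14). Among the splits that parted every pair the highest other counts of lists were 10, 11, 16 and 13, so there the labels alone reached 17 and 16 lists between genotypes but not those of the responses. Splits that mix the labels thus called many lists. Each such split keeps part of the labelled difference, so its list calls can come from that difference or from structure between libraries. The rest of the labelled difference adds to the spread within its parts, which lowers its count of genes. For the interaction the labels gave 0 genes, which 100 of 100 splits drawn from 200 reach by construction, so these say nothing of chance. At least 6 lists came from 93 of 100 splits (highest other 21). Splits that give the treatments unequal numbers of KO libraries carry the genotype difference into this contrast, so these splits cannot decide on chance. With same-numbered pairs kept together and the block within genotype, the labels gave 5 lists. Other ways of giving genotype to the pairs gave from 1 to 11 lists, so chance cannot be excluded for the list responses. With the block within genotype 1 of 10 ways of giving genotype to the 6 same-numbered pairs of libraries reached 41 genes (highest other 5).

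Erythroid, neutrophil, macrophage and monocyte markers were higher in KO libraries. A lower share of DCs would raise all other cell types alike. Over the B, T and NK lists the mean KO minus WT difference ran from -0.37 log2 (T cells, treated, SE 0.13) to 0.38 (B cells, untreated, SE 0.12). The erythroid list had 4.43 untreated (SE 0.28) and 4.91 treated (SE 0.17). The protocol depleted B, T and NK cells, so what remained of them can depend on that depletion. Their values therefore cannot decide on a rise of all other types alike, and a lower share of DCs stays open. Macrophage and monocyte lists stood at 1.97 to 3.24 log2 CPM in WT. The rises of the erythroid and neutrophil lists, low in WT, differed by 0.72 log2 untreated (SE 1.16) and 1.26 treated (SE 1.05). In KO libraries number 2 exceeded number 3 in 13 of 14 neutrophil genes, with a lower quartile of 2.69 log2 or above. The macrophage median went the other way (-0.73 untreated and -0.48 treated). Neutrophil RNA that differs between preparations remains a candidate explanation for the neutrophil part. A difference in the number of neutrophils would look the same, so these values cannot decide between them. Cells carried along by the preparation and a changed makeup of the spleen in the KO animals cannot be told apart. The lowest KO erythroid level lay 4.03 log2 above the highest WT level, and preparation and genotype coincide. A biological difference by genotype stays open and was not tested apart from the preparation.

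Slc29a3 counts remained in KO libraries. A swap of single libraries was argued against, since 0 of 12 libraries lay closer to the mean of the other genotype in genes called in the other treatment (1074 and 2243 genes). A swap of both libraries of a same-numbered pair would place the same error in both treatments, which this test may not show. Splits that mixed the genotype labels called at most 0 genes untreated and 6 treated, against 1852 and 2016 with the labels. An exchange of all WT and all KO labels would leave the test of single libraries as it is and stays open, with Slc29a3 in KO at no more than 0.74 of WT and the difference not past the threshold. A deletion that leaves part of the transcript cannot be told apart from other explanations at the level of gene counts, where the lower ratio of KO to WT was 0.72.

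The 41 genes with a different response under the block within genotype included 4 of 20 macrophage markers (Adgre1, Hmox1, Slc40a1 and Spic; 0.06 expected, odds ratio 95.8, two-sided Fisher's exact p = 2.7e-07). Of the 41, 27 already differed between untreated genotypes, 23 of them higher in KO. That p treats the markers as independent, while their estimated correlation was 0.474. Untreated Adgre1 and Slc40a1 were at 22.8 and 13.8 CPM in WT and 136 and 97.1 CPM in KO. Hmox1 (611 ± 243 and 1060 ± 665 CPM) and Spic (115 ± 20.9 and 151 ± 56.6 CPM) differed less. Of 10 ways of giving genotype to the 6 pairs, 1, the labels, placed 4 macrophage markers among the 41 genes with the smallest p (highest other 1), though 10 ways cannot give a share under 0.1. A mixture of cells that differs with genotype, each type with its own response, remains a candidate explanation, and a changed response of the DCs themselves was not tested apart from it.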

How the results depend on the processing

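The window of 1 Mb, the fits with the sex term, those without the libraries numbered 1, and the blocked fits of lists and named genes were chosen after the data were seen. No call of a gene in a comparison of groups turned its sign in any setting. The response counts held in 11 of 14 settings each; library totals alone gave 5024 in WT and 5721 in KO, and at least 1 log2 gave 982 and 1373, by its construction. The genotype counts held in 12 of 13 (1084 with at least 1 log2, untreated) and 11 of 13 settings (1093, and 1074 with only the groups compared). The replicate block within genotype gave 4561 and 4986 genes and 41 in the interaction, and changed no list call, and no gene call that the results print, other than those given beside it there. Across genotypes, libraries of the same number correlated with r from 0.079 to 0.323 and 10 of 12 were closest to their own number; the replicate block over all groups gave 3547, 4137, 2584 and 2942 genes, and Slc29a3 at -0.4781 log2 in treated cells (edgeR adjusted p = 0.0383). For the interaction, 2 genes passed without a filter and 6 in DESeq2; causes were not tested. With an estimated correlation 5, 5, 1, 1 and 0 lists passed in the 5 contrasts, and with fry 0 in the interaction. Over all 5 contrasts fry, which does not set members against other genes, kept 43 of 58 list calls and lost 15. Without the libraries numbered 1, 10 interaction lists passed.

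With each library left out, counts ran from 1509 to 2936 (WT response), 2132 to 3651 (KO response), 863 to 2123 (untreated), 1028 to 2888 (treated) and 0 to 8 (interaction), with fewer libraries by construction. The induced response difference ran from 0.1869 to 0.4229 log2 and the repressed one from -0.2538 to 0.04608. Interaction lists ran from 4 to 12. For list neutrophils, interaction (KO response minus WT response), the median was -1.636 without KO_STm replicate 2 (camera adjusted p = 0.0198) and 1.225 without KO_untreated replicate 2 (0.0336). KO number 2 had the highest neutrophil level in both treatments (4.98 and 5.02 log2 CPM, other KO libraries 1.87 to 3.07), so leaving out either unbalanced the contrast. Slc29a3 ran from -0.6561 to -0.3544 untreated and -0.6548 to -0.3292 treated. Within 5 Mb of Slc29a3 the odds ratios were 0.79 and 0.85, and within 1 Mb, above 1. Of 7608 values of named genes with a library left out, 6876 kept their side of the threshold, 707 were weaker, 25 stronger and 0 reversed.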

Other observations

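No test was run on the values of this part. Libraries numbered 1 differed from numbers 2 and 3 in all 4 groups. Xist, the transcript that silences the X chromosome in females, had 0, 0, 0 and 1 counts in libraries 1 of untreated WT, treated WT, untreated KO and treated KO, against 10384 to 18147 in the other 8. The 4 Y-linked genes had 6238, 5592, 4392 and 5897 counts in libraries 1 and 0 in the others. B and plasma cell genes were 1.60 to 1.95 log2 higher in number 1 than in the mean of numbers 2 and 3, and T cell genes 1.72 to 2.11 log2. The mean B cell level was 3.65, 3.75, 3.80 and 4.01 log2 CPM in libraries 1, against 1.59 to 2.36 in the others. Interferon response genes differed by -1.02 log2 in treated KO and by -0.18 to 0.00 in the other groups. Macrophage genes differed by -0.76 and -0.90 in untreated and treated KO and by 0.58 and 0.49 in WT, and cholesterol synthesis genes by 0.75 and 0.77 in KO and 0.03 and -0.14 in WT.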
